A study of Mus musculus with 12 samples.

How the data were processed

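m5C peaks were studied in brain RNA of male C57 mice aged 12 to 14 weeks after middle cerebral artery occlusion (MCAO) or a sham operation (Sham). Per the labels' protocols, the RNA was broken into fragments of about 200 nt, m5C-bearing fragments were captured with an antibody kit, and IP and input libraries were made with a whole-RNA kit and sequenced on a NovaSeq. Groups and replicate numbers were taken from the sample labels, which give 3 IP and 3 input libraries per group, 12 libraries in all.

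Per the submitters' processing notes, cutadapt 1.9.3, STAR, HISAT2 2.0.4 and the mm10 build were used, without their roles or order. The deposited files were 18 peak lists, each for 1 of the 6 numbered samples and 1 of 3 RNA classes (mRNA, lncRNA and circRNA), so peaks were called per sample and not on pooled samples. Peak names begin with MACS per the file headers and entries, and the version and settings of the caller are not given in the sources used here. For each peak the authors gave a fold enrichment, a ratio that was 2.00 or more in every list. The deposited score was the negative log10 of the peak p multiplied by 10, and was 50 or more in every list. The deposited false discovery rate was in percent and ran from 0 to 22.68%, so the lists were not limited to a low rate. These peak values are the authors' own and were used to rank or filter peaks within a list and to describe peaks and lists, without a test between lists. The highest deposited peak number per animal lay between 217597 and 289507, far above the number of peaks in any list, so the lists hold part of the called peaks. Sham replicate 2 had the highest of these numbers, the highest false discovery rate and, in each class, the lowest median fold enrichment. No read counts are in the lists, so the depth per library is unknown and no counting interval can be given. The lists give no strand for peaks, so a gene and an overlapping antisense gene cannot be told apart by strand.

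Starts were converted to count from 1. A peak repeated for several transcripts was counted once, and 6 lines without a peak were removed. Such a peak kept the gene name and type of its first line, so any other gene or type listed for it was not counted. This concerns the lncRNA lists, where 27911 to 31676 lines gave 6557 to 7262 peaks. Gene and circRNA names were used as the files give them, and 17606 of 18459 mRNA gene names (95.4%) matched a gene of the reference table (assembly GRCm38.p6), which was used for gene IDs, synonyms and the genomic span of genes. No per-sample columns outside the map of columns were left unused (0). Peaks of the 6 lists of a class were merged into regions where they overlapped by at least 1 bp, and a region or gene was present in an animal if that animal's list held a peak in it. The overlap of a pair of lists was the Jaccard index, the regions in both over the regions in either.

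Per-animal counts, shares of peaks and members of gene lists were compared between groups with a two-sided exact permutation test of the difference in mean over all 20 assignments of the 6 animals, whose smallest p is 0.1. Benjamini-Hochberg adjustment ran over the 27 gene lists and over the shares of peak types. List members among the genes of a group were tested with Fisher's exact test. Before the data were examined, the gene lists, the comparisons of peaks, genes, regions, overlap and list members, and the rule for named genes were fixed. The rule named all m5C writers, erasers and readers, up to 4 members of each list with the largest difference in the number of animals with a peak, the 10 mRNA genes, 5 lncRNAs and 5 circRNAs per direction with peaks in all animals of a group and no animal of the other, ranked by the lowest within-list percentile of fold enrichment, and the 5 genes with the most peaks. Of the list members, the text names those that differ by at least 2 animals. Some items that the rules select are not reported here. Members named for a peak in all 6 animals or in none, Malat1, Snhg11 and the genes of terms were chosen after their values were seen. A ranking of group-specific regions inside genes by the same percentile was added after seeing the data.

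Shares of peak types, peaks per gene and further tests were added after seeing the data. Peaks per gene were compared with limma 3.58.1 in R 4.3.3 on the square root of peak numbers scaled to list length, for genes with a mean of at least 1 peak per animal, with a trended empirical Bayes fit and Benjamini-Hochberg adjustment at 0.05. On simulated peak numbers for 11041 genes, this fit recovered 78.0% of genes with 4-fold more peaks, 16.0% with 2-fold more, 24.0% with 0.25-fold and 0% with 0.5-fold, and called 1 of 10842 unchanged genes. The changes were planted only in genes with a mean of at least 3 peaks, and the simulated numbers had Poisson spread alone. Gene Ontology and KEGG terms of 5 to 500 genes, as the mRNA lists annotate them, were tested by Fisher's exact test in genes specific to a group against genes with a peak in exactly 3 animals. On simulated data a planted term with a large excess ranked 1 and 0 null terms were called. Smaller excesses were not simulated, so the power of this test for terms with few genes is unknown. The merging of peaks was also tested on simulated lists and found 200 of 200 planted regions in each direction. It called 0 regions that were not truly specific to that group in the simulation. The simulated peaks of a site always overlapped, so both results were certain in advance and check only the counting. Listed peaks were as short as 1 bp, and shared sites whose peaks miss each other were not simulated. The simulated sites lay too far apart to merge with each other, so the merging of neighbouring peaks was not tested. Gene lists and terms were set against 10000 random gene sets matched on genomic span in 50 bins. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 ran the other steps.

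Alternatives were the stronger 50% of each list by fold enrichment, the same number of strongest peaks from every list, a reciprocal overlap of 50% for a shared region, each animal left out in turn, and the replicate number as a block. The planned tests of IP over input per site, of input expression and of the position of mRNA peaks on transcripts were not run, because read counts and an annotation of transcript parts were not used here. Outliers were not sought, since each group held 3 samples.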

Results

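The series profiled 5-methylcytosine (m5C), a methyl mark on RNA, in mouse brain after experimental stroke, and asked which mRNAs, long non-coding RNAs (lncRNAs) and circular RNAs (circRNAs) carry it differently. In m5C immunoprecipitation sequencing, RNA fragments bound by an m5C antibody (IP) are sequenced beside the unselected fragments (input), and a peak is a stretch where the IP exceeds the input. Male C57 mice had the middle cerebral artery blocked with a filament for 60 min (MCAO) or a sham operation (Sham). Each group held 3 numbered samples, called animals here, with 1 peak list per animal and RNA class, 18 lists in all. The labels name brain without the hemisphere and do not say that the numbers mark separate animals, so p-values measure the spread between these samples. The lists give no read counts, so the depth of each library is unknown, and a gene without a listed peak may still carry m5C. A weak peak near the lowest listed fold enrichment of 2.00 counted as presence like a strong one. With 3 animals per group a two-sided exact permutation test cannot give a p below 0.1, so no comparison by that test could pass 0.05.

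Peaks on mRNA covered most genes, and several neuronal lists had peaks on most members in every animal. Of 18459 gene names with a peak in any animal, 7654 (41.5%) had one in all 6. Of the pan-neuronal list, 23 of 24 members had a peak in all 6 animals, and the remaining one, the glycolytic enzyme Eno2, had none in any. Voltage-gated ion channels and calcium handling reached 27 of 30 members, Wnt, Notch and axon guidance 28 of 33, cortical and hippocampal markers 13 of 14, and oligodendrocyte and myelin genes 14 of 20. Immediate early genes, which neurons induce on activity, reached 13 of 30, among them Arc, Egr1, Junb and Npas4, and heat shock and unfolded protein response genes 11 of 24, among them Hspa1a, Hsp90aa1 and Xbp1. Random lists matched on gene span gave means of 11.6, 18.8, 18.03, 5.93, 7.25, 6.26 and 5.18 members for these 7 lists. Adjusted p lay between 0.00260 and 0.0423 in this permutation of lists, a comparison added after seeing the data. The random lists were drawn from all 21900 protein-coding genes of the reference, of which 78.4% had a peak in any animal. The span of a gene includes introns, and transcript length was not matched. Expression was not analysed either, so transcript length and expression of the listed genes in brain remain untested reasons for these counts. Other neuronal lists did not pass, with 18 of 23 glutamate receptor and excitatory genes against a matched mean of 14.7 (adjusted p = 0.385), 16 of 24 GABA receptor and inhibitory genes against 12.1 (adjusted p = 0.338) and 6 of 12 striatal markers against 4.93 (adjusted p = 0.881). Neutrophil genes had 1 of 16 members in all 6 animals against a matched mean of 3.35 (adjusted p = 0.395), and S100a8 and S100a9, abundant neutrophil calcium-binding proteins, had no peak in any animal.

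The genes with the most peaks encode very large proteins. Dst, a cytoskeletal linker, had a mean of 58.8 peaks per animal, Syne1, which ties the nucleus to actin, 55.3, Utrn, a relative of dystrophin, 47.5, Ubr4, a ubiquitin ligase, 43.7, and Macf1, which links microtubules to actin, 40.7. Syne1 had 59.7 ± 2.89 peaks in MCAO and 51.0 ± 3.61 in Sham animals (SD, n = 3), and Dst 58.7 ± 1.15 and 59.0 ± 5.29. No difference of these 5 genes between the groups passed the test (limma adjusted p between 0.942 and 0.993). In limma's test of 11197 genes, 0 had a different number of peaks at an adjusted p of 0.05 and 535 (4.78%) had an unadjusted p under 0.05. The smallest adjusted p was 0.942. This test was added after seeing the data. On simulated data it recovered 78.0% of genes with 4-fold more peaks but 16.0% of those with 2-fold more. For fewer peaks it recovered 24.0% at 0.25-fold and 0% at 0.5-fold. These changes were planted only in genes with a mean of at least 3 peaks and with Poisson spread alone, so recovery among all genes tested may be lower.

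The MCAO lists held more mRNA peaks than the Sham lists, over about the same number of genes. They had 49294 ± 1469 peaks against 45473 ± 1594 (SD, n = 3), a ratio of 1.08, and the lowest MCAO list (47728) was longer than the highest Sham list (46551). Genes with a peak numbered 12839 ± 81.7 and 12833 ± 295, so peaks per gene were 3.84 ± 0.0990 in MCAO and 3.55 ± 0.202 in Sham animals. The exact permutation p was 0.1 for peaks and for peaks per gene, the smallest the design allows, and 1 for genes. With the same number of strongest peaks from each list, the difference in genes was -417 genes, MCAO minus Sham.

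**Figure D1:**
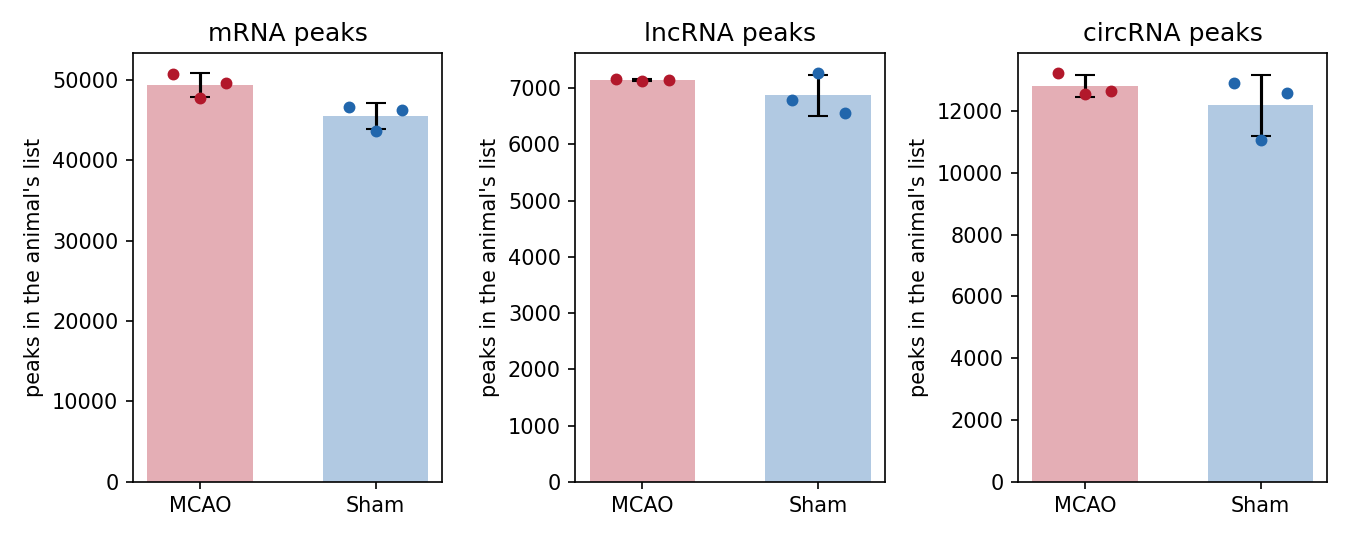
Number of peaks in each animal's list (vertical axis) for mRNA, lncRNA and circRNA, with 1 point per animal, bars at the group mean and error bars of 1 SD (n = 3). The 3 MCAO lists of mRNA hold 47728 to 50641 peaks and the 3 Sham lists 43642 to 46551, while the ranges overlap for lncRNA and circRNA.

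Positions of the peaks varied widely from animal to animal, and MCAO animals shared the most. The 6 mRNA lists merged into 114653 regions, of which 50797 (44.3%) were in 1 animal and 11190 (9.76%) in all 6. The mean Jaccard index was 0.354 (SD 0.0259) over the 6 pairs of animals within groups and 0.355 (SD 0.00940) over the 9 pairs between groups. The difference, within minus between, was -0.000111, and 5 of the 10 splits of the animals gave one as high (exact permutation p = 0.5). That mean within groups joins pairs on either side of those between groups. The MCAO pairs (mean 0.378, lowest 0.374) all lay above the pairs between groups, which ran from 0.343 to 0.370, and the Sham pairs (mean 0.331, highest 0.339) all lay under them.

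**Figure D2:**
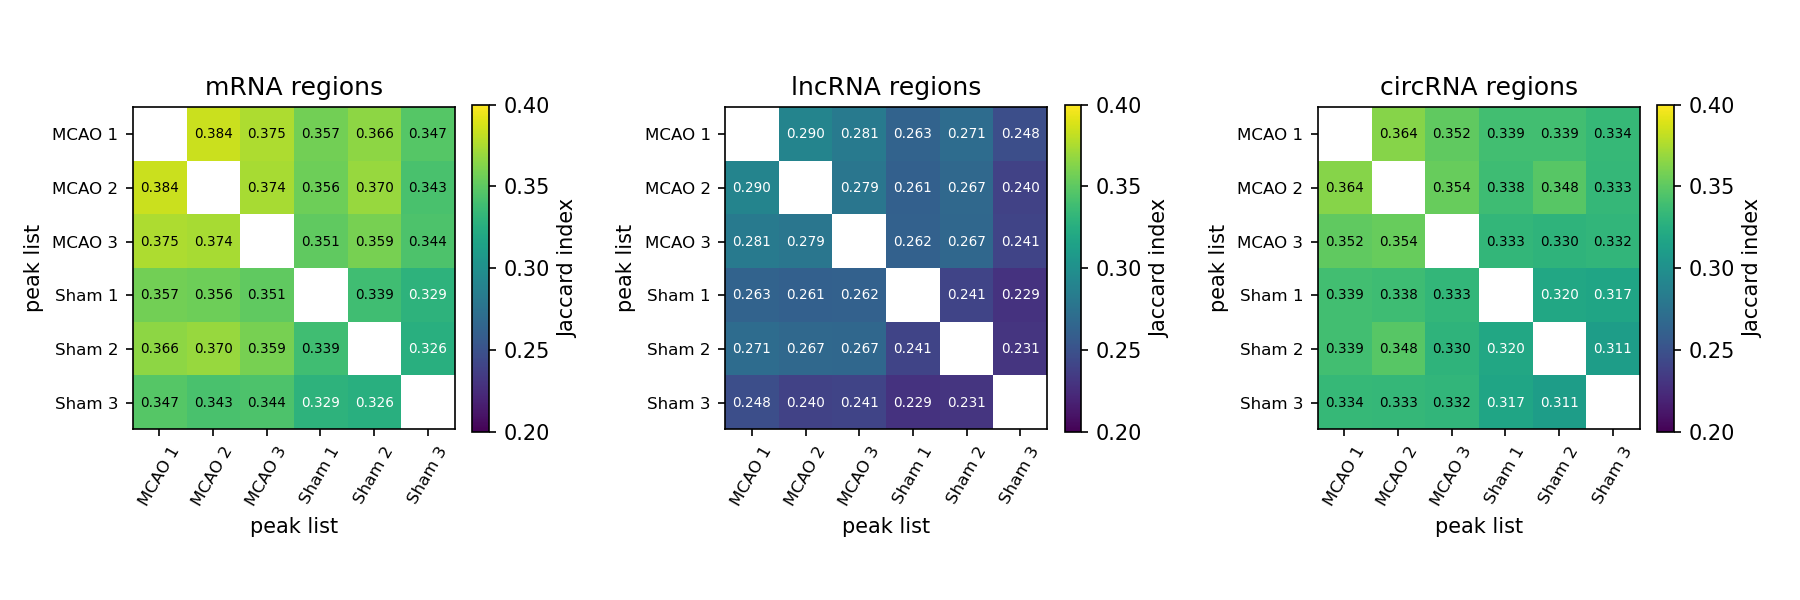
Jaccard index (colour and printed value) of each pair of animals' lists for mRNA, lncRNA and circRNA regions, with the animals on both axes. MCAO pairs of mRNA lists average 0.378, Sham pairs 0.331 and pairs across groups 0.355.

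Group-specific regions lay almost wholly in genes that carried m5C peaks in the other group too. All 3 MCAO and no Sham animals had a peak in 950 mRNA regions, and all 3 Sham and no MCAO animals in 402. An even spread of the 13369 regions found in 3 animals over all trios would put 668 on each side. Of the 950 regions, 924 (97.3%) were in genes with another peak in a Sham animal. Of the 402, 387 (96.3%) were in genes with a peak in an MCAO animal. No baseline was computed for these shares. Of 18459 genes with a peak, a mean of 12839 had one per MCAO animal and 12833 per Sham animal. High shares could therefore arise for almost any set of regions. Among the strongest MCAO regions, ranked by a rule added after seeing the data, were those in Col6a2, a collagen VI chain (chromosome 10, 76611948 to 76612001), Pld5, Rab36 and Pds5b, a cohesin regulator. The strongest Sham regions were in Myo18a, an unconventional myosin (chromosome 11, 77840681 to 77840809), Dlg5, a scaffold of cell polarity (chromosome 14, 24137130 to 24137239), Foxj2, Atp2b3, a plasma membrane calcium pump, and Gpatch4. Each of these genes had peaks in all 6 animals except Pld5, which had them in 3 MCAO and 2 Sham animals. Coordinates are on mm10, and the part of the transcript was not analysed here. With lists of equal length the counts were 697 and 495 regions.

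**Figure D3:**
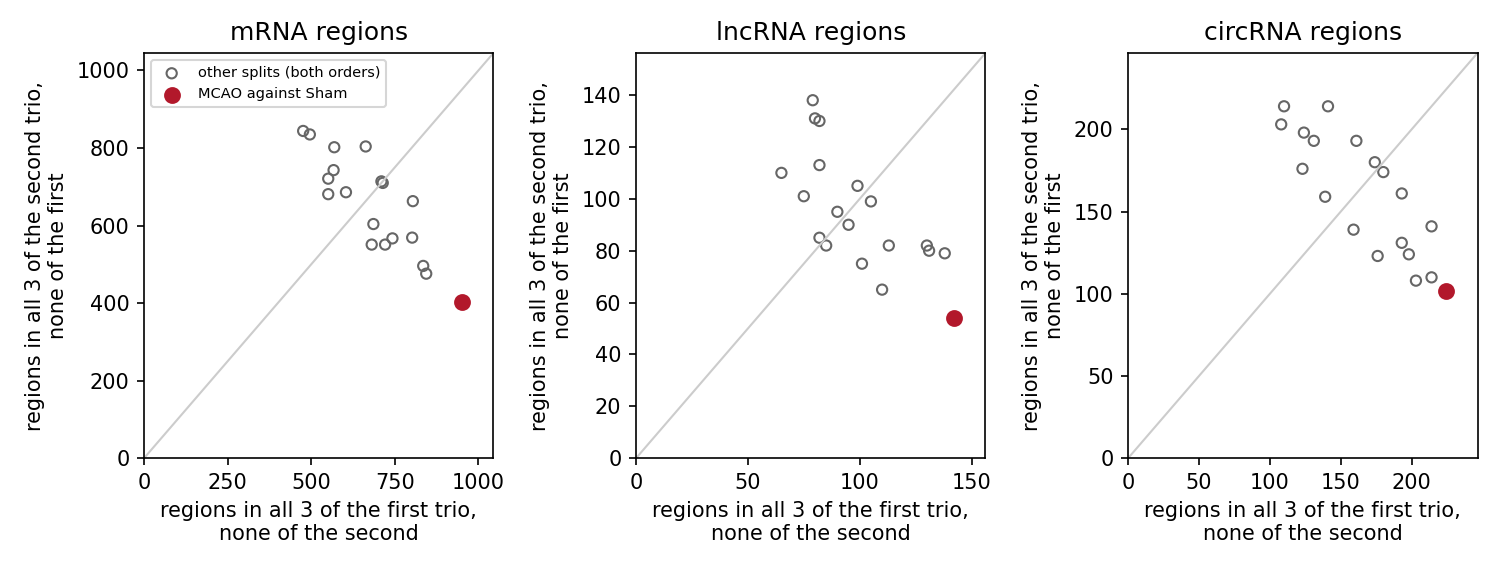
Regions present in all 3 animals of a first trio and no animal of the second (horizontal axis) against the reverse (vertical axis) for every split of the 6 animals, with MCAO as the first trio for the filled point. The filled point of mRNA lies at 950 and 402 regions, and the diagonal marks equal counts.

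Genes with a peak in all animals of a group and no animal of the other included single genes of lactate export, Notch signalling and mitosis. A peak in all 3 MCAO and no Sham animals was found in 89 genes, and the reverse in 91, against 89.35 on each side under an even spread of the 1787 genes found in 3 animals. With lists of equal length the counts were 66 and 116. Among members of the fixed lists, the first set held Slc16a3, which exports lactate (chromosome 11, 120957913 to 120958180), Hes1, a repressor induced by Notch (chromosome 16, 30066872 to 30067336), Rpl6, a protein of the large ribosomal subunit (chromosome 5, 121204481 to 121204552), and Ndufs3, a subunit of respiratory complex I (chromosome 2, 90904584 to 90904827). The second set included Cdk1, the mitotic kinase (chromosome 10, 69338459 to 69338596), Birc5, which acts in chromosome segregation and survival (chromosome 11, 117849237 to 117849461), and Emcn, an endothelial sialomucin (chromosome 3, 137430596 to 137430722). The 10 MCAO genes with the strongest peaks were Casp16, Sftpc, the lung surfactant protein C, Commd3, Nkapl, Rpl6, Pot1b, a telomere-binding protein, Gimap5, a GTPase of lymphocyte survival, Elf4, Spata24 and Mcm8, a helicase of DNA repair. The 10 Sham genes were Chil1, a chitinase-like protein of reactive astrocytes, Fbxl22, Serinc5, Pla2g1b, a secreted phospholipase, Srms, Ildr1, Haus4, a subunit of augmin, Edn3, endothelin 3, Trim6 and Gpaa1. Coordinates are those of the gene's strongest peak in a single animal, whereas presence counted any peak in the gene. The interval given need not have held a peak in the other animals of the group. Presence in 3 against 0 animals has an exact p of 0.1 for any gene, so none passed a test alone.

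Genes of the stress response and of inflammation carried peaks in both groups. Immediate early genes with a peak numbered 24 ± 1 of 30 members in MCAO and 22.3 ± 0.577 in Sham animals (SD, n = 3, exact p = 0.2), with Maff and Gadd45b in 3 MCAO and 1 Sham animals and Dusp6, a phosphatase of ERK, in 2 and 0. Heat shock and unfolded protein response genes numbered 19.3 ± 1.15 and 17.3 ± 2.52 of 24 (exact p = 0.4), with the heme oxygenase Hmox1 and the chaperones Hspb8 and Hspe1 in 3 and 1. Cytokines, chemokines and their signalling numbered 19 ± 1.73 and 16.3 ± 2.89 of 36 (exact p = 0.3). Ptgs2, which makes prostaglandins, was in 3 and 1 animals, Tnf in 0 and 2, and Il1b, Ccl4, Cxcl1 and Tlr4 were among 9 members with no peak in any animal. Microglia and macrophage genes numbered 17 ± 2.65 and 15.7 ± 3.51 of 26 (exact p = 0.7), with the protease Ctss in 3 and 1, Spp1 and Mrc1 in 2 and 0, and Lgals3 in 0 and 2. Neutrophil genes numbered 4 ± 2.65 and 5.67 ± 1.53 of 16 (exact p = 0.5), with the matrix protease Mmp9 in 1 and 3 animals and Camp in 0 and 2.

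Genes of neurons, glia and vessels carried peaks in similar numbers in both groups, and no such gene list separated them in the full peak lists. Every animal had peaks on 23 pan-neuronal genes (exact p = 1). Glutamate receptor and excitatory genes numbered 20.7 ± 0.577 in MCAO and 21.3 ± 1.15 in Sham animals of 23 members (SD, n = 3, exact p = 0.6), with Grm7 in 1 and 3 animals. GABA receptor and inhibitory genes numbered 19.7 ± 1.15 in both groups of 24 (exact p = 1), with Gabrd in 3 and 1, and ion channels 29.3 ± 0.577 and 28.7 ± 0.577 of 30 (exact p = 0.6). Astrocyte genes numbered 19 ± 2.65 and 19 ± 2 of 26 (exact p = 1), with the glutamate transporter Slc1a3 in 3 and 1 animals, the water channel Aqp4 in 1 and 3, and Emp1 in 0 and 2. The strongest peak had a fold enrichment of 8.49 in Slc1a3, 10.14 in Emp1 and only 3.58 in Aqp4. Oligodendrocyte and myelin genes numbered 18.3 ± 1.15 and 17.3 ± 0.577 of 20 (exact p = 0.4), with Mog and Mal in 3 and 1 and Cldn11 in 1 and 3. Endothelial genes numbered 17.3 ± 1.15 and 18.7 ± 1.53 of 22 (exact p = 0.4), with Emcn in 0 and 3 and Ly6a in 0 and 2, and pericyte, smooth muscle and fibroblast genes 12.7 ± 1.15 and 11.7 ± 1.53 of 16 (exact p = 0.6), with Col3a1 in 3 and 1. Choroid plexus and ependymal genes numbered 7.33 ± 0.577 and 7 ± 1.73 of 14 (exact p = 1), with Folr1 in 2 and 0, and red blood cell genes 3 ± 0 and 3.33 ± 1.15 of 8 (exact p = 1). Striatal markers numbered 10.3 ± 1.53 and 8.33 ± 1.53 of 12 (exact p = 0.3), cortical and hippocampal markers 13.7 ± 0.577 in both groups of 14 (exact p = 1), and markers of thalamus, hypothalamus and hindbrain 7.67 ± 1.15 and 7 ± 1 of 14 (exact p = 0.7).

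Genes of cell death, metabolism and growth gave the following numbers with a peak in MCAO and Sham animals. Apoptosis and p53 response genes numbered 19 ± 1 and 20.7 ± 2.08 of 26 (SD, n = 3, exact p = 0.5), with the survival factor Mcl1 in 0 and 2 animals and Cycs, cytochrome c, in 2 and 0. The peaks of both were weak, with a highest fold enrichment of 4.41 in Mcl1 and 4.1 in Cycs. Ferroptosis, necroptosis and antioxidant genes numbered 17.7 ± 1.15 and 17.3 ± 2.08 of 27 (exact p = 1), with the transferrin receptor Tfrc and the glutathione enzyme Gclm in 3 and 1, Gpx4, which limits lipid peroxides, in 2 and 0, and the necroptosis effector Mlkl in 0 and 2. Hypoxia and glycolysis genes numbered 22 ± 1 and 20.7 ± 2.52 of 27 (exact p = 0.7), with Slc16a3 in 3 and 0 and the hypoxia-induced genes Ddit4 and Ankrd37 in 2 and 0. Oxidative phosphorylation genes numbered 21 ± 3 and 18.3 ± 2.08 of 32 (exact p = 0.4), with Ndufs3 in 3 and 0 and Uqcrc2 in 2 and 0. The highest fold enrichment was 9.81 in Ndufs3 and 4.36 in Uqcrc2. Cytosolic ribosomal proteins numbered 18.3 ± 1.15 and 14.7 ± 3.21 of 37 (exact p = 0.2), with Rpl14 in 3 and 1 and Rplp2 in 0 and 2. Proliferation genes numbered 13.7 ± 2.52 and 16.7 ± 3.21 of 24 (exact p = 0.3), with Cdk1 and Birc5 in 0 and 3 and Ccnb1 in 0 and 2. Wnt, Notch and axon guidance genes numbered 32 ± 1 and 30.3 ± 0.577 of 33 (exact p = 0.2), with Hes1 in 3 and 0 and Ctnnb1, beta-catenin, in 3 and 1. Over all 27 lists the smallest adjusted p was 0.9. Fisher's exact test found no list enriched among the 89 MCAO or 91 Sham genes, with proliferation genes in the Sham set, 2 members, at the smallest adjusted p (0.307).

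**Figure D4:**
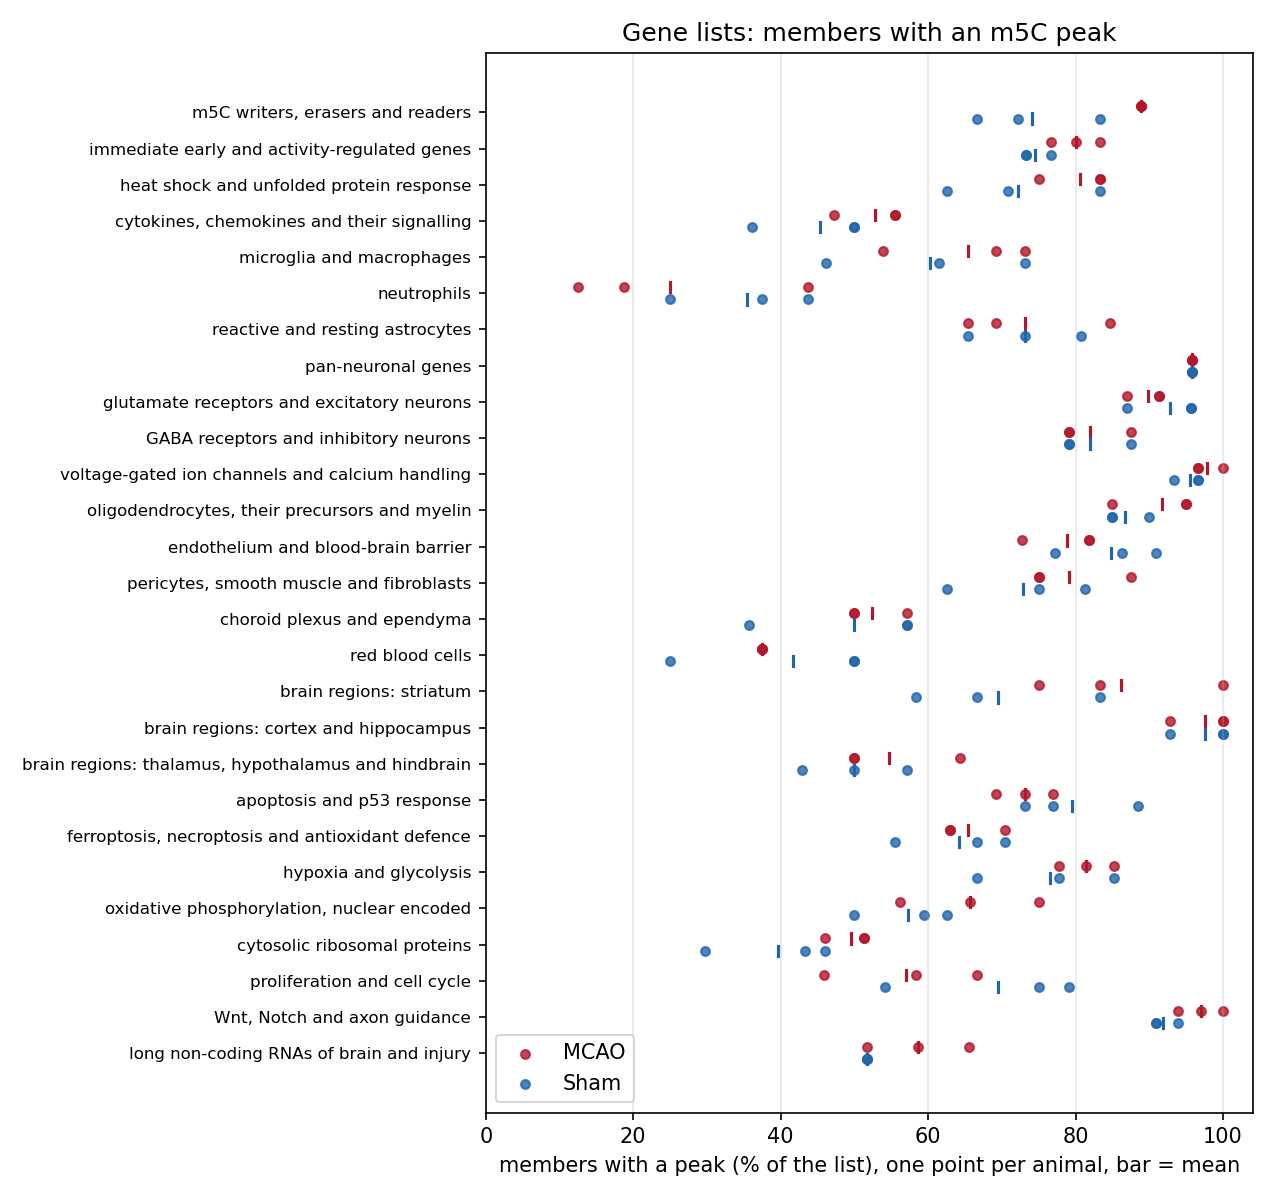
Members of each fixed gene list with a peak, in percent of the list (horizontal axis), with 1 point per animal and a vertical bar at the group mean. The m5C writers, erasers and readers are the list whose MCAO animals (16 of 18 members each) all lie above the Sham animals (12 to 15 members).

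The transcripts of the m5C machinery carried peaks themselves. Of 18 writers, erasers and readers, 10 had a peak in all 6 animals. Random lists matched on gene span gave a mean of 6.92 members (adjusted p = 0.385 in the permutation of lists). The 10 were the methyltransferases Nop2, Nsun2 and Nsun4, the demethylating oxygenases Tet1, Tet2 and Tet3, and the binding proteins Alyref, Ybx1, Ybx2 and Fmr1. The mitochondrial methyltransferase Nsun3, the ribosomal RNA methyltransferase Nsun5 and the splicing factor Srsf2 had peaks in 3 MCAO and 1 Sham animals, and Nsun7 in 3 and 2. The strongest peak of Nsun3 had a fold enrichment of 5.53 and was in a Sham animal. Those of Nsun5, Srsf2 and Nsun7 had 17.23, 16.36 and 16.5. Alkbh1, an oxygenase that acts on m5C, had peaks in 2 and 1 animals, Rad52 in 2 and 2, and Nsun6 and Trdmt1, a tRNA methyltransferase, in 1 and 1. Each MCAO animal had 16 members with a peak, against 13.3 ± 1.53 in Sham animals (SD, n = 3, exact permutation p = 0.1, adjusted p = 0.9 over 27 lists). It was the single list of 27 without overlap between the groups, where chance gives 10% of lists, or 2.7, without ties and fewer with the ties these counts hold. With the same number of strongest peaks from each list the difference was 1.67 members, against 2.67, and the groups overlapped (exact p = 0.4). They also overlapped in the stronger 50% of each list, at 12, 14 and 14 members in MCAO and 10, 12 and 11 in Sham animals.

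Well-known brain lncRNAs carried peaks in both groups. Of 29 lncRNAs of brain and injury, 7 had a peak in all 6 animals, namely Neat1, Meg3, Rian, Snhg1, Snhg12, Sox2ot and Firre, and Malat1 had one in 2 MCAO and 3 Sham animals. Dlx6os1, an antisense RNA of interneuron development, had peaks in 3 and 1, Snhg11 in 3 and 1, Snhg5 and Snhg15 in 2 and 0, and Gas5, a growth arrest transcript, in 0 and 2. The highest fold enrichment was 8.65 in Dlx6os1, 5.06 in Snhg5, 4.41 in Snhg15 and 5.45 in Gas5. The list had 17 ± 2 members with a peak in MCAO and 15 ± 0 in Sham animals (SD, n = 3, exact p = 0.4). Genes with a peak in all MCAO and no Sham animals numbered 86, and those with the strongest peaks included transcripts listed as Cwc22 (chromosome 2, 77936593 to 77936727, overlapping an exon in sense), AK005616, Gm16437 and Il20rb. The reverse numbered 62, led by Gm10552 (chromosome 1, 85604324 to 85604440, antisense within an intron), Cux2, Doc2g, Prpsap1 and Cyp4f41-ps. Coordinates are those of the strongest peak in a single animal. Names of coding genes here stand for the non-coding transcripts to which the lists assign peaks at those loci. Where such a transcript overlaps a coding exon in sense, the fragments could also stem from the coding mRNA. No peak number was in both the lncRNA and the mRNA list of an animal, but the assignment itself was not tested.

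Across all lncRNAs the lists held 7150 ± 19.1 peaks in MCAO and 6871 ± 359 in Sham animals (SD, n = 3, exact p = 0.4), on 5071 ± 36.1 and 5050 ± 282 genes (exact p = 1). Peaks per gene were 1.41 ± 0.0136 and 1.36 ± 0.0107 (n = 3, exact p = 0.1). Without Sham replicate 3 the difference in peaks was 121 and without Sham replicate 2 it was 474, against 278 with all animals. In comparisons of peak types, added after seeing the data, peaks on lncRNAs that overlap an exon of a coding gene in sense made up 66.1 ± 0.550% and 63.4 ± 2.24% (exact p = 0.1, adjusted p = 0.22 over 11 shares of lncRNA and circRNA peaks), and the difference of 2.65 percentage points was 1.46 without Sham replicate 2. Intergenic lncRNAs made up 13.5 ± 0.757% and 15.9 ± 1.66% (exact p = 0.2), and intron sense-overlapping ones 3.25 ± 0.0721% and 3.43 ± 0.105% (exact p = 0.1). Natural antisense lncRNAs (7.31% and 7.35%), intronic antisense (7.60% and 7.67%) and bidirectional ones (2.28% and 2.26%) differed by less than the SD. Of 20942 regions, 1106 (5.28%) were in all 6 animals, 142 in all MCAO and no Sham animals and 54 in the reverse. The mean Jaccard index was 0.259 within and 0.258 between groups (exact permutation p = 0.5), where the first joins MCAO pairs at 0.283 and Sham pairs at 0.234.

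Several circRNAs had m5C peaks in all animals of a single group. Those of all MCAO and no Sham animals numbered 70, led by circRNAs of the host genes Zbtb34 (chromosome 2, 33410581 to 33412495, minus strand), Smox, which oxidises spermine (chromosome 2, 131511984 to 131520268, plus strand, exonic), Ttll11 (chromosome 2, 35889265 to 35944959, minus strand, exonic), Fam19a5 (chromosome 15, 87726702 to 87727488, plus strand, intronic) and Vopp1 (chromosome 6, 57762435 to 57790035, minus strand, exonic). The reverse numbered 29, led by circRNAs of Ntm, a neuronal adhesion molecule (chromosome 9, 29875926 to 29877165, minus strand, intronic), the locus XLOC_009581 (chromosome 16, 48126396 to 48142551, minus strand), Plekha2 (chromosome 8, 25052360 to 25063986, minus strand, exonic), Tab3, a kinase adaptor of inflammatory signalling (chromosome X, 85609390 to 85630544, plus strand), and Acvr1, a BMP receptor (chromosome 2, 58458885 to 58468660, minus strand, exonic). An even spread of the 815 circRNAs found in 3 animals would put 40.75 on each side, and with lists of equal length the counts were 49 and 31. Of 6989 circRNAs with a peak, 2553 (36.5%) had one in all 6 animals.

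Across all circRNAs the lists held 12801 ± 357 peaks in MCAO and 12176 ± 984 in Sham animals (SD, n = 3, exact p = 0.5), on 4832 ± 62.1 and 4610 ± 289 circRNAs (exact p = 0.3). Both differences rested on Sham replicate 2, and without it they were 65.5 peaks and 58.8 circRNAs, against 625 and 223. The circRNA list of this replicate had the lowest median fold enrichment (5.35) and the highest false discovery rate (22.12%). Exonic circRNAs made up 57.9 ± 0.356% and 55.6 ± 1.58% of peaks, those overlapping a gene in sense 35.8 ± 0.450% and 37.5 ± 1.33%, and intronic ones 4.73 ± 0.210% and 5.23 ± 0.183% (n = 3, exact p = 0.1 and adjusted p = 0.22 for each). The exonic difference of 2.32 percentage points was 1.41 without Sham replicate 2. Antisense circRNAs (0.889% and 0.874%, exact p = 0.8) and intergenic ones (0.669% and 0.785%, exact p = 0.3) were few. CircRNAs without a database entry took 51.1% and 51.9% of peaks. Of 32008 regions, 3011 (9.41%) were in all 6 animals, 224 in all MCAO and no Sham animals and 102 in the reverse, and the mean Jaccard index was 0.336 within and between groups (exact permutation p = 0.4), where the first joins MCAO pairs at 0.356 and Sham pairs at 0.316. A share of 67.8 ± 0.729% of circRNA peaks in MCAO and 65.4 ± 2.37% in Sham animals carried the number of a peak that the mRNA list also held (n = 3, exact p = 0.1), with the same fold enrichment in 100% of them and the same coordinates in 73.9 to 75.7%.

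Gene Ontology and KEGG terms, which the series design names, were tested in the mRNA genes of a single group, a test specified after seeing the data. The Sham genes included the kinetochore and chromosomal passenger genes Apitd1, Birc5, Cdca8 and Cenpl, 4 of 91, annotated to the centromeric region of chromosomes, and the MCAO genes included the proteasome genes Psma1, Psmb4 and Psmg3. Neither term passed, and of 722 terms 0 were enriched in either direction, with a smallest adjusted p of 1 (Fisher's exact test). Without MCAO replicate 3, 2 terms passed in the Sham genes, PDZ domain binding (adjusted p = 0.0354, with Cript, Kif14, Pdzk1, Slc26a6, Sntg2 and Ushbp1) and secretory granule (adjusted p = 0.0409, with Cartpt, Cdc42, Pla2g1b, Rab37, Tor1a and Zp2). No term passed in the MCAO genes of this setting or in any other setting. The adjustment ran within each setting and direction, so the search over settings was not adjusted for.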

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

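Tests of peaks per gene, of terms, of shares of peak types and of the overlap within MCAO against within Sham were chosen after the result was seen, and so were their alternatives and the same number of strongest peaks for genes per animal. The other alternatives were fixed before the data were examined. An exact test of 3 against 3 cannot pass 0.05, so the alternatives show direction and size, not a change of call. The unknown read depth limits every count, and the tests of IP over input per site, of input expression and of peak position on transcripts were not run.

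The exonic shares kept their direction in the stronger 50% of peaks and with the same number of peaks, and the higher overlap among MCAO than among Sham animals for mRNA also with a reciprocal overlap of 50%. For these and for mRNA peaks per animal, leaving out an animal cannot turn the direction, and taking 50% of each list or the block leaves the direction of peaks per animal as it is by construction. Peaks per animal of lncRNA and circRNA kept their direction without each animal in turn. Without Sham replicate 2 the difference in the lncRNA exon sense-overlapping share was 1.46 percentage points, against 2.65, and in the circRNA exonic share 1.41, against 2.32. The difference in genes per animal, MCAO minus Sham, turned with the same number of strongest peaks to -417 for mRNA and -120 for lncRNA. Without each animal in turn it ran from -130 to 163 for mRNA and from -87.5 to 181 for lncRNA. The overlap within minus between groups also had no stable sign. In the stronger 50% of peaks it was 0.00159 for mRNA and 0.00131 for circRNA, and with the same number of peaks 4.13e-05 and 0.000533. Without each animal in turn it ran from -0.0116 to 0.0159 for mRNA, from -0.0130 to 0.0166 for lncRNA and from -0.0106 to 0.0124 for circRNA, negative each time an MCAO animal and positive each time a Sham animal was left out, since MCAO pairs overlap more and Sham pairs less than the mean pair between groups. The cause of the other sign changes was not tested.

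In the stronger 50% of each list, regions in all MCAO and no Sham animals numbered 462 for mRNA, 63 for lncRNA and 103 for circRNA, those of the reverse 197, 26 and 54, and lncRNA genes 45 and 28. Fewer peaks by construction lower these counts. Leaving out an animal raises them, since fewer animals must hold the peak. Regions of MCAO then numbered 1726 to 2740 for mRNA, 219 to 431 for lncRNA and 396 to 699 for circRNA, and those of Sham 780 to 1879, 105 to 313 and 197 to 591. Genes of MCAO numbered 186 to 256 for mRNA, 166 to 231 for lncRNA and, as circRNAs, 132 to 148, and those of Sham 181 to 298, 107 to 232 and 58 to 108. Gene lists without overlap between groups numbered 3 in the stronger 50% and 2 to 6 without each animal in turn. The 3 were pan-neuronal genes (1.33 members more in MCAO), hypoxia and glycolysis (3.33 more), and Wnt, Notch and axon guidance (2.33 more). In the full lists these differences were 0, 1.33 and 1.67 members, in the same order. A count of 3 is near the 2.7 lists that chance gives without ties. With the same number of strongest peaks, only Wnt, Notch and axon guidance was without overlap (2.33 members more in MCAO). The m5C machinery was not among the lists without overlap in the stronger 50% or with the same number of strongest peaks, where its difference was 1.67 members. Leaving out an animal cannot make separate ranges overlap. Genes with a different number of peaks stayed at 0 in limma in all 10 alternatives, with 377 to 741 at an unadjusted p under 0.05. Enriched terms numbered 0 to 2 without each animal in turn.

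The groups share replicate numbers, and the labels do not say that these pair the animals. Lists of the same number had a mean Jaccard index of 0.357 and those of other numbers 0.353 for mRNA, 0.257 and 0.258 for lncRNA, and 0.340 and 0.334 for circRNA. In the order mRNA, lncRNA and circRNA, 3, 2 and 4 of 6 lists were closest to the list of their own number in the other group, so not every list matched its number and the samples were treated as unpaired. With the number as a replicate block the exact sign-flip p of mRNA peaks per animal was 0.25, the smallest it allows, and 3 gene lists had 3 paired differences of 1 sign (m5C machinery, striatum and oxidative phosphorylation). In limma the block left 0 genes called and 544 at an unadjusted p under 0.05.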

Other observations

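The tests of terms, of matched random sets, of the overlap among MCAO against among Sham lists, of the splits, of each explanation and of peak numbers shared between RNA classes were chosen after the results were seen. The counts of regions, genes and list members and their alternatives were planned, except the same number of strongest peaks for genes per animal.

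Regions marked in every animal point to the RNAs on which m5C peaks were most regular. The 11190 mRNA regions in all 6 animals lay in 4661 genes, 25.3% of the genes with a peak. Among genes annotated to the synapse, 267 of 476 (56.1%) held such a region, among those of the postsynaptic density 139 of 204 (68.1%), and among those of dendrites 211 of 390 (54.1%). Chromatin binding genes had 203 of 416 (48.8%) and actin binding genes 162 of 311 (52.1%). In all 470 of 5085 terms passed (Fisher's exact test), with an adjusted p of 5.78e-44 for synapse. Long genes hold more peaks, and random sets matched on gene span gave 164 synapse genes where 260 were observed, 76.5 postsynaptic density genes where 139 were observed and 119 chromatin binding genes where 198 were observed. The 60 terms examined in this way were those with the smallest p in Fisher's exact test, so they were picked for their excess in these same genes. Of them, 50 reached a permutation p of 0.0001, the smallest that 10000 draws can give. Genomic span includes introns, and transcript length was not matched. Expression was not analysed here, so long transcripts and highly expressed genes remain untested reasons for these counts.

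MCAO lists shared more mRNA regions with each other than Sham lists did, with a gap in mean Jaccard index of 0.0462. Longer MCAO lists could give such a gap, but with the same number of strongest peaks from each list it was 0.0462 again, and a single aberrant Sham list is argued against by the best Sham pair, 0.339, below the lowest MCAO pair, 0.374. Each list may instead share more or less with any other list: 1 value per list explained 96.9% of the variance of the 15 indices for mRNA, and all 3 Sham lists were closer to MCAO lists than to each other. Such a value could come from read depth or antibody capture, which the lists do not measure directly, or from the MCAO and Sham states, which stayed untested. Median fold enrichment of mRNA peaks was 6.96, 6.51 and 7.2 in MCAO and 6.68, 5.94 and 7.59 in Sham lists. These ranges overlapped, but the fold is not a direct measure of capture, so capture stays open.

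The m5C machinery had 2.67 more members with a peak in MCAO than in Sham animals, and 1.67 more with the same number of strongest peaks from each list. Of 10000 random lists matched on peaks per gene, 2.22% had a difference as large (mean 0.277, SD 1.13), which over 27 lists gives 0.599 lists, so chance among the lists examined may account for it. In the stronger 50% of peaks the difference was 2.33, above 50% of its former value by less than the SD of random lists, so peaks near the calling threshold stay open as a source. Effects of ischemia on m5C of Nsun3, Nsun5 or Srsf2 transcripts stay open and untested.

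Peaks listed on circRNAs could stem from the linear transcripts of their host genes, and the lists cannot decide this. Of exonic circRNA peaks, 93.0% in the lowest and 93.9% in the highest animal carried the number of a peak in the mRNA list, and all lay inside the circRNA's bounds. Exonic circRNAs use exons of the host gene, so a high share would arise from linear or circular RNA alike. Some peaks of a shared number had other coordinates in the mRNA list, so lying inside the bounds may come from the assignment. Fragments of an exon do not show whether it was circular, and the peak lists hold no back-splice reads, so m5C on the circRNAs themselves stays open. No biological explanation was tested.

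The 6 animals make 10 splits into 3 and 3, too few for a share under 0.05. For regions in all animals of a group and no animal of the other, both directions together, 4 of 10 splits gave as many for mRNA (1352, highest other 1467), 5 for lncRNA (196, highest other 217) and 4 for circRNA (326, highest other 355). By direction, no other trio had as many regions to itself as the MCAO trio (950, 142 and 224 for mRNA, lncRNA and circRNA) or as few as the Sham trio (402, 54 and 102). The classes are not independent, since 62.6 to 68.2% of circRNA peaks per animal carried the number of an mRNA peak. With lists of equal length the mRNA counts of these 2 trios narrowed to 697 and 495. For genes, both directions together, 5 of 10 splits gave as many for mRNA (180, highest other 193), 7 for lncRNA (148, highest other 173) and 1 for circRNAs (99, highest other 90). Gene lists without overlap numbered 1 (highest other 4, 6 of 10 splits as many). Genes with a different number of peaks and enriched terms numbered 0 in the real split and at the highest 0 in the other splits. A count of 0 is reached by any of the 10 splits, so it says nothing about chance.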
